A study of Homo sapiens with 6 samples.

How the data were processed

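Total RNA of LOX melanoma cells was measured on 6 Affymetrix oligonucleotide arrays, 3 with mock vector and 3 with seprase siRNA. The deposited values are probe set intensities on a linear scale, 1 per probe set and array, which the authors had already summarised from the probes. From the values, the authors had scaled every array to one trimmed mean: after removal of the lowest and highest 2% of intensities, the means were 250.11 to 250.15. The software, background correction and detection calls behind the intensities are not given in the sources used here, nor is a genome build, so no coordinates are printed. An intensity has no count behind it, and precision comes from the number of arrays alone. The share of probe sets with an intensity under 10 was 29.5%, 36.1% and 45.4% with mock vector and 28.3%, 24.8% and 37.3% with siRNA, so dim probe sets were measured over unequal ranges. The ratios of 3′ to 5′ control probe sets were 0.84 to 0.92 for *GAPDH* and 0.86 to 0.97 for *ACTB*.

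Groups and replicate numbers were taken from the sample titles and descriptions. An offset equal to the 25th percentile of all intensities (4.9) was added before log2, so log2 changes understate the change of dim genes. By a rule fixed before the data were examined, the deposited scaling would have been kept had the array medians and 75th percentiles on the log2 scale lain within 0.3. They ranged over 1.41 and 0.58, and the log2 values were therefore quantile normalized. The 68 array control probe sets and those with a mean under the 40th percentile were left out, which left 13329 probe sets for 8116 named genes. Probe sets were named through the platform annotation, with symbols updated by gene number through RefSeq genes of assembly GRCh38.p14. In it 19071 probe sets had 1 symbol (19059 matched by gene number), 1043 had several and were left unnamed, and 2107 were unnamed here. For gene lists a gene was read from its brightest tested probe set.

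Groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with a variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) over the 6 arrays without a block. *FAP* was read first as a check of the labels, with an exact permutation test beside the limma fit. Of 28 gene lists fixed before the data were examined, 27 had at least 5 tested members and were tested with camera at a preset correlation of 0.01; camera with an estimated correlation and fry were alternatives. The lists hold 674 genes, of which 599 were on the arrays and 470 were tested. Both tests were tested on simulated data in which 200 of 13329 probe sets, or 1 list of 27, were changed: the shifted list was called with 0 others. That list was shifted by log2 −1, far more than the heat shock median of −0.12, so the test does not cover changes of the size reported here. Noise was drawn independently for each gene, so the 0 others called says nothing of lists whose members correlate. The heat shock members had an estimated correlation of 0.34.

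The named genes were fixed by rule: the 12 largest rises and falls among probe sets past the threshold whose groups do not overlap or, where fewer than 5 passed in a direction, the 8 with the highest test statistic in that direction. To these were added *FAP*, *DPP4*, up to 4 called members of each list and the 3 members with the lowest p of each list that camera called. Since no probe set passed, 8 genes per direction were named.

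The titles number the arrays 1 to 3 in both groups. Deviations from the group means of arrays with the same number correlated across probe sets at 0.28, 0.10003 and 0.50, each above the 0.1 set for treating numbers as pairs, the second only barely. Arrays of different numbers reached 0.31 (mock vector 2 with siRNA 1) and 0.21 (mock vector 1 with siRNA 2), so only the pair numbered 3 stood clear. Deviations from a mean of 3 arrays cancel out, so a shift shared by the arrays numbered 3 pushes the others the opposite way. Arrays 1 and 2 of both groups then correlate positively whatever their pairing, so passing the limit does not show that they pair. All numbers were still treated as pairs under the limit set, by the correlations alone, although the counts of calls of both fits had been seen by then. The main comparison stayed without the block, as fixed before the data were examined, and the blocked fit is given beside it where it changes a call. Nothing in the labels says what a number stands for. The alternatives were the deposited scaling, median centring, other offsets (10th and 40th percentile), no filter or one at the 60th percentile, no variance trend, array weights, the replicate block, a test per probe set without shared variance, the mean of a gene's probe sets, and leaving out each array in turn. After the data were seen, a term for the arrays numbered 3, leaving out both of them, and either that or the block with an estimated correlation were added. Figures were drawn with matplotlib 3.10.9.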

Results

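RNA of LOX cells, an established human melanoma line, was profiled on 6 oligonucleotide arrays, each holding 22283 probe sets. On 3 arrays the cells carried a mock vector that expressed green fluorescent protein, and on 3 arrays the vector also expressed a small interfering RNA (siRNA) against seprase. Seprase, the product of *FAP* (fibroblast activation protein alpha), is a cell-surface serine protease of the dipeptidyl peptidase family that cleaves gelatin. The series concerns the part seprase plays in the spread of LOX cells, and the comparison that its labels set up is seprase siRNA against mock vector. All arrays had been brought to one trimmed mean signal (250.11 to 250.15), but their median signals were 40.8, 29.7 and 15.8 with mock vector and 42.3, 50.2 and 28.2 with seprase siRNA. The labels do not say that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

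*FAP*, the targeted gene, fell in the cells with seprase siRNA. Its 1 probe set read signals of 429, 763 and 788 with mock vector (660.0 ± 200.2, SD, n = 3) and of 105, 157 and 45.2 with the siRNA (102 ± 55.9, SD, n = 3). Every siRNA array thus lay below every mock array, and the mean signal with siRNA was 15.5% of that with mock vector. The log2 change was −2.81 (SE 0.41; 95% confidence interval −3.76 to −1.87), a 7.03-fold difference on the scale of log2 signal plus offset. In this fit *FAP* had both the lowest p and the largest fold of all 13329 probe sets tested; with both arrays numbered 3 left out, *SNRNP27* (−2.56) and *ICAM1* (−2.42) had larger changes than *FAP* (−2.30). *SNRNP27* also had a lower p than *FAP* there and without mock vector array 3 alone. As the single gene planned for testing it had an unadjusted limma p of 1.07e-04. Adjusted over the list alone, that is over the 7 tested proteases of the DPP4 family, limma gave an adjusted p of 0.00075; adjusted over all probe sets tested, it gave 0.9997. An exact two-sided permutation test of 3 arrays against 3 gave p = 0.1, the smallest it can give. *DPP4*, which encodes the protease that forms complexes with seprase, was read by 3 probe sets, all too dim to be tested, with signals of at most 14.7 on any array.

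**Figure D1:**
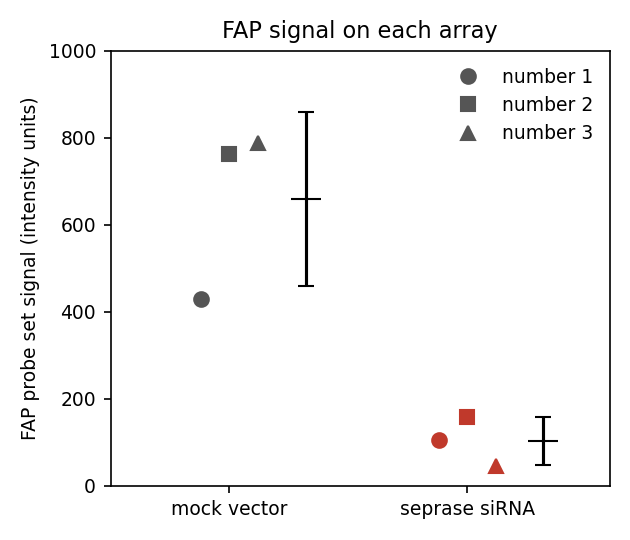
Signal of the *FAP* probe set (vertical axis, intensity units) on each of the 6 arrays, by group (horizontal axis); marker shapes give the replicate number, and bars show the mean and SD of 3 arrays. The siRNA arrays lie between 45.2 and 157, all below the mock arrays, whose lowest signal is 429.

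*FAP* aside, no single gene was told apart between the groups. No probe set passed an adjusted p of 0.05 in limma over the 13329 tested, in either direction. At an unadjusted p under 0.05 there were 276 probe sets, or 2.07%, where chance gives 5%; with the replicate number as a block there were 537 (4.03%), and without both arrays numbered 3 there were 793, again with 0 past the adjusted threshold. A test of each probe set with its own variance also called 0, with 412 at an unadjusted p under 0.05. Among the 8954 probe sets left out of the test, adjusted by themselves, 2 passed. Both were array controls for Cre, lower with siRNA (log2 −0.29 and −0.33, limma adjusted p = 0.013 and 0.011). The 3 arrays of one group lay wholly above the 3 of the other for 473 probe sets higher and 426 lower with siRNA, together 6.74% of those tested, where chance gives 10%. Simulated changes in data with the spread of these arrays, number effects included, were called for 6% of 2-fold, 48% of 4-fold and 96% of 16-fold changes, and with the replicate block for 26%, 84% and 100%. There 200 probe sets changed at once, which eases the adjusted threshold, so a gene that changes alone would be called less often. *FAP*, at 7.03-fold, was itself not called over all probe sets (limma adjusted p = 0.9997, and 0.227 with the block).

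Of the 8 genes with the highest test statistics on the side of higher values with siRNA, none passed the threshold (adjusted p = 0.9997 for each). *HMGA1*, an architectural chromatin protein, read 976 ± 153 with mock vector and 1506 ± 53.9 with siRNA (SD, n = 3; log2 +0.69, SE 0.19), and its other probe set differed by +0.30. *KCNN4*, a calcium-activated potassium channel, read 678 ± 186 against 1200.0 ± 173 (log2 +0.89, SE 0.26). *MT1E*, a metal-binding metallothionein, read 5499 ± 666 against 8409 ± 1386 (log2 +0.69, SE 0.18) on a probe set that can bind related transcripts. With median centring of the arrays these 3 log2 changes were +0.17, +0.38 and +0.14. *MYO9B*, an unconventional myosin, differed by +1.35 (SE 0.38), while its other probe sets gave +0.25 and +0.18. *ANXA2P3*, a pseudogene of annexin A2, differed by +1.78 (SE 0.50). *TESK2*, a kinase of the cofilin pathway, *NFATC4*, a calcineurin-dependent transcription factor, and *ECE2*, an endothelin-converting enzyme, differed by +1.71, +1.75 and +1.71 at mean signals of at most 56.0 in either group, and a second *NFATC4* probe set gave −0.51.

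On the side of lower values with siRNA, none of the genes that followed *FAP* passed the threshold either (adjusted p = 0.9997 for each). *TRIB1*, a pseudokinase that directs protein degradation, read 361 ± 44.8 with mock vector and 151 ± 36.3 with siRNA (SD, n = 3; log2 −1.36, SE 0.26). *SNRNP27*, a spliceosome component, read 402 ± 244 against 94.6 ± 18.2 (log2 −2.07, SE 0.44), and its other probe set gave −1.46. *SEC24A*, part of the coat of vesicles leaving the endoplasmic reticulum, differed by −1.10 (SE 0.30) and −0.99 on its 2 probe sets. *GORASP2*, a Golgi stacking protein, differed by −0.83 (SE 0.22), with −0.45 and −0.10 on its other probe sets. *CDIPT*, the enzyme that makes phosphatidylinositol, differed by −0.84 (SE 0.23), and *MMACHC*, of cobalamin metabolism, by −1.93 (SE 0.42) at mean signals of 39.0 and 10.7. *ICAM1*, an intercellular adhesion molecule, gave −1.78 (SE 0.48) on 1 probe set, at mean signals of 59.8 with mock vector and 16.6 with siRNA. Its other probe set gave +0.28 (SE 0.49), at 63.9 and 90.8.

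**Figure D2:**
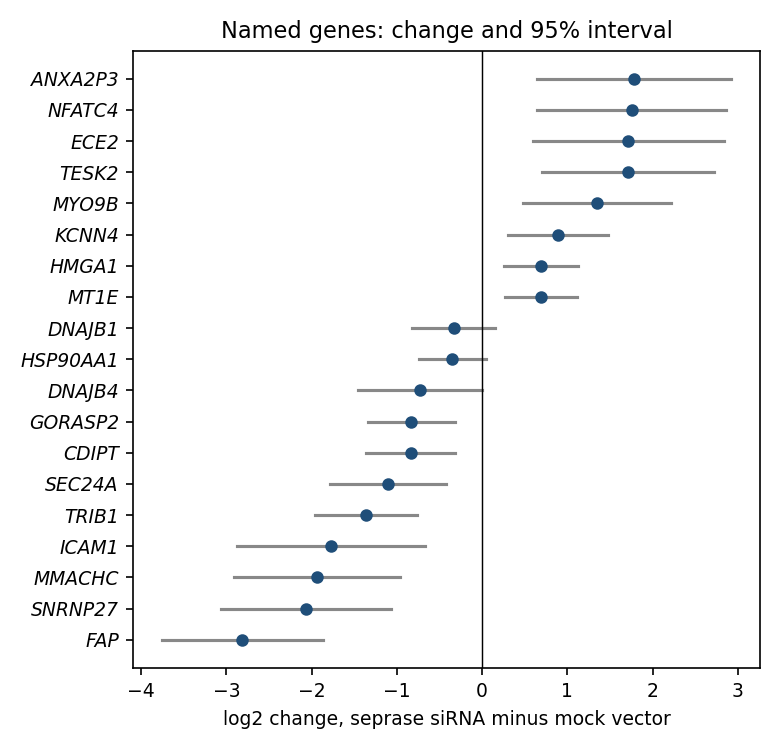
Log2 change (horizontal axis, seprase siRNA minus mock vector) of 19 named genes, with bars for the 95% confidence interval from limma before adjustment. *FAP* lies lowest at −2.81, and the others range from −2.07 to +1.78.

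Among 27 gene lists fixed beforehand, heat shock genes, the chaperones and co-chaperones of protein folding, were called lower with siRNA as a list. All 12 tested members lay below 0, with a median of −0.12 and a mean of −0.21 on the log2 scale (camera in limma, adjusted p = 0.0096), although 0 members passed over all probe sets and 0 when adjusted over the list alone. With an estimated correlation between members, the list's adjusted p = 0.88, and no list was called. The cytosolic chaperone *HSP90AA1* differed by −0.35 (SE 0.17), and the co-chaperones *DNAJB1* and *DNAJB4* by −0.34 (SE 0.21) and −0.73 (SE 0.32). Their values came to −0.13 without siRNA array 3, −0.17 without mock vector array 1 and −0.43 without mock vector array 3, respectively. Other probe sets gave −0.30, −0.26 and −0.53 for *HSP90AA1*, −0.27 for *DNAJB1* and −1.08 (SE 0.30) for *DNAJB4*. Without mock vector array 1 the list's adjusted p was 0.473, and without seprase siRNA array 3 it was 0.516, so either array decided the call. The same list had a median of −0.34 on the arrays numbered 3 against the other arrays, which turned with the scaling (−0.16 with the deposited scaling, +0.63 with median centring).

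The replicate number shared by the groups was also kept as a block, although the values do not show that numbers 1 and 2 pair. With it, 3 lists were called, all lower with siRNA. They were heat shock (adjusted p = 0.0027), cell cycle genes (31 of 42 below 0, median −0.15; adjusted p = 0.00079) and inflammatory cytokines with NF-kB targets (13 of 21 below 0, median −0.24; adjusted p = 0.013). With the block and an estimated correlation, the adjusted p = 0.76 for each of them. The cell cycle list stood at −1.29 on the arrays numbered 3 against the others, and its median difference between the groups was −0.41 in the pair numbered 3 and −0.09 and +0.06 in the pairs numbered 1 and 2. For the inflammatory list these medians were −0.73, +0.04 and +0.04. With the block, 4 inflammatory genes passed when adjusted over the list alone and 0 over all probe sets. The cytokines *CXCL3* (log2 −1.78), *LIF* (−2.01) and *IL1A* (−1.28) were lower with siRNA in each of the 3 pairs, and *IL24*, a cytokine of the IL-10 family, was higher in each (+0.60). *LIF* averaged a signal of 19.4 on the arrays numbered 1 and 2, near the lowest level tested (15.1). In the pair numbered 3 it read 253 with mock vector and 18.9 with siRNA, and *CXCL3* read 502 and 101.

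The lists closest to the study's subject were not called over the 6 arrays with quantile normalization. Median centring moved the median of all tested probe sets to −0.30, so its counts of members above 0 are low for most lists. Relative to that median, it put integrins at −0.04, extracellular matrix at +0.04, metalloproteinases at −0.004 and the interferon response at −0.05. Actin and invadopodia genes lay at −0.18, DPP4 family proteases at −0.20 and the melanocyte lineage at +0.37. These positions do not allow for brightness: probe sets as bright as the metallothioneins had a median of −0.51 under this centring. List calls made only with the deposited scaling or median centring thus cannot be told apart from scaling. Of the DPP4 family proteases, 1 of 7 tested members, *FAP*, passed when adjusted over the list alone, and the others differed by −0.57 (*DPP6*) to +0.16 (*APEH*); the list's adjusted p was 0.169, and in the mixed form of fry, which asks whether genes change in either direction, 0.035. The list was called lower with median centring of the arrays. Both results include *FAP*, the gene that the siRNA targets. The list was not tested without it, so they do not show a change of the other members. Matrix metalloproteinases and their inhibitors had 9 of 13 members above 0, and 5 with median centring (median +0.09, adjusted p = 0.678), among them the metalloproteinase *MMP19* at +1.69 (SE 0.79). This list was called without mock vector array 3, and was the 1 list called, higher with siRNA, without both arrays numbered 3 (adjusted p = 0.016), a call lost with an estimated correlation (0.740 without these arrays, 0.936 over all 6). Actin and invadopodia genes had 16 of 27 members above 0, with a median of +0.02 but a mean of −0.07 and a test towards lower values (adjusted p = 0.678). With the deposited scaling 11 members lay above 0 and the list was called, and with median centring 1 did. Integrins and their partners split 8 to 8, with 2 above 0 under median centring (adjusted p = 0.904); the list held the focal adhesion adaptor *PXN* at +0.66 (SE 0.21) and the collagen receptor subunit *ITGA2* at −0.82 (SE 0.36). Extracellular matrix genes had 14 of 24 members above 0, and 7 with median centring (adjusted p = 0.879). In that list *TGFBI*, a secreted adhesion protein, differed by −1.24 (SE 0.41) and *FN1*, fibronectin, by +0.52 (SE 0.19). Genes of the melanocyte lineage had 8 of 11 members above 0 (adjusted p = 0.540) and were called higher with the deposited scaling and with median centring. Among them were the transcription factor *PAX3* at +0.83 (SE 0.35) and the proteoglycan *CSPG4* at −0.999 (SE 0.43), both dim. These examples were chosen after their values were seen. The interferon response list, which covers genes that double-stranded RNA can induce, had 15 of 27 members above 0, and 7 with median centring (median +0.03, adjusted p = 0.904), with 0 members past the threshold. Markers of fibroblasts, leukocytes and epithelia gave adjusted p values of 0.473, 0.753 and 0.753, and endothelial markers had 4 tested members, too few to test. Outside these lists and the 3 called with or without the block, the adjusted p values ran from 0.216 to 0.985.

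**Figure D3:**
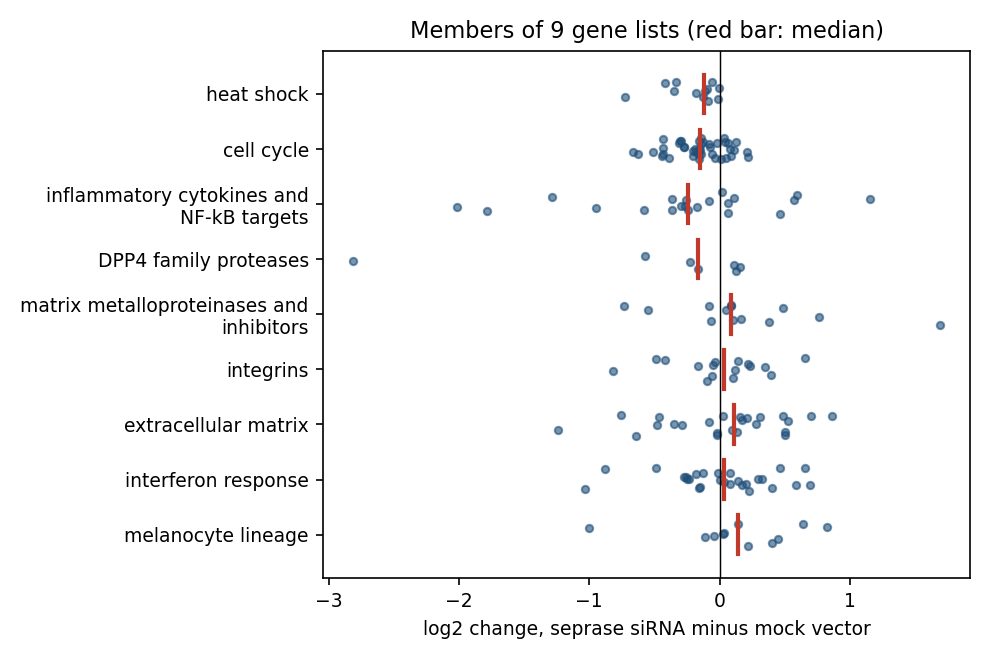
Log2 change (horizontal axis, seprase siRNA minus mock vector) of each tested member of 9 gene lists (rows); points are genes, red bars the medians. All 12 heat shock genes lie below 0, and *FAP* is the point at −2.81 among the DPP4 family proteases.

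The arrays numbered 3 were set apart from the other arrays more than the groups were from each other. The first principal component held 47.4% of the variance and placed mock vector array 3 and seprase siRNA array 3 at 62.1 and 52.3, with the other arrays between −42.8 and −19.8. With the group kept in the model, 1402 probe sets differed between the arrays numbered 3 and the other arrays at an adjusted p under 0.05 (521 higher, 881 lower). The count and its split moved with the scaling, to 2777 with the deposited scaling (559 higher, 2218 lower) and 3996 with median centring (3313 higher, 683 lower). The same comparison called 0 probe sets for number 1 and 0 for number 2. There the arrays numbered 3 stayed among the other arrays and widened their spread. Those counts of 0 thus cannot exclude an effect of number 1 or 2. Of 42 cell cycle genes, 36 were lower on the arrays numbered 3 and 0 higher, and with median centring 16 were lower and 1 higher.

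**Figure D4:**
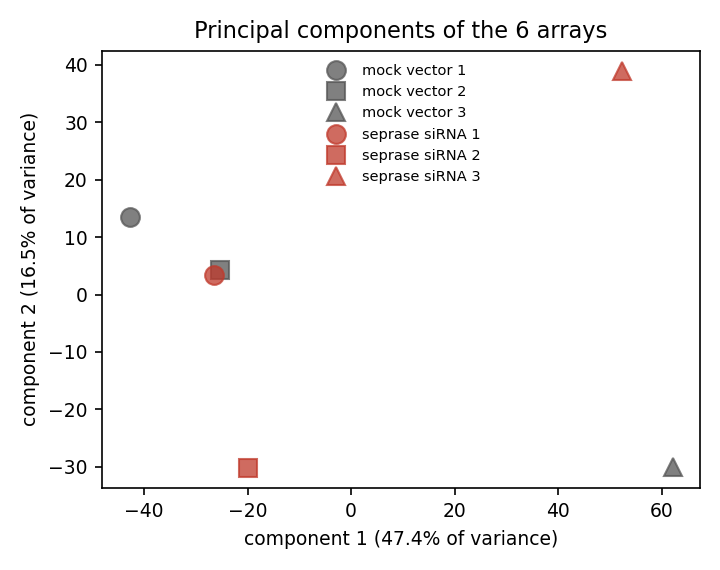
Principal components 1 and 2 (axes, with their share of variance) of the log2 values of all tested probe sets; colours give the group and marker shapes the replicate number. The arrays numbered 3 of both groups lie at 52.3 and 62.1 on component 1, and the other arrays at −19.8 or lower.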

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

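The term for the arrays numbered 3, the fit without both of them, and that fit or the block with an estimated correlation were chosen after seeing the data; the other settings were planned. *FAP* kept its direction and its call as the single planned gene under all 18 alternatives run, with a log2 change of −3.20 to −2.30 and an unadjusted p of at most 0.0043 and, without each array in turn, −3.13 to −2.48. The count of probe sets called was 0 under all 18 alternatives, the replicate block included, with lowest adjusted p values of 0.067 to 0.99997. The 18 other named genes kept their direction and stayed short of the threshold in all 319 values, though median centring took *MT1E* to +0.14, *HMGA1* to +0.17 and *KCNN4* to +0.38. The count of gene lists moved most: from 1 (0 higher, 1 lower) to 8 with the deposited scaling (1 higher, 7 lower), 5 with median centring (1 higher, 4 lower), 2 with the 60th percentile filter, 3 with the replicate block or the term for the arrays numbered 3, and 0 without a variance trend, with array weights, with fry and with an estimated correlation, with or without the block or both arrays numbered 3. With the block, the list members that passed when adjusted over the list alone went from 1 to 5, and no other call changed. The deposited scaling moved the median of all tested probe sets to +0.16 and median centring to −0.30. Without 1 array the count was 1 to 4: 1, 3 and 4 without mock vector array 1, 2 or 3, and 2, 2 and 3 without siRNA array 1, 2 or 3. The heat shock list lost its call without a variance trend (adjusted p = 0.141), with array weights (0.443), without the arrays numbered 3 (0.239, with a median of −0.11 beside −0.12 over all arrays), with an estimated correlation (0.881), with fry (0.915) with the block and an estimated correlation (0.759) and without the arrays numbered 3 and with an estimated correlation (0.740). Without 1 array its adjusted p was 0.00029 to 0.516, above 0.05 without mock vector array 1 (0.473) and siRNA array 3 (0.516); over all 22 alternatives it ran from 4.2e-07 to 0.915, and beyond the single array and the correlated members, weighed under the other observations, the cause was not tested. Signal over background limits the dim genes: the lowest level tested was a signal of 15.1.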

Other observations

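The tests on RNA degradation, on the scaling of the arrays numbered 3, on the heat shock list and on shared hybridisation, the comparison of the metallothioneins by pair, and all genes named here, were chosen after the results were seen. On the arrays numbered 3 of both groups, cell cycle genes were lower than on the other 4 arrays. *PCNA*, the sliding clamp of DNA replication, averaged a signal of 1957 on the arrays numbered 1 and 2 and 307 on those numbered 3 (log2 −2.57, SE 0.17, adjusted p = 0.00028), and the replication licensing factor *CDC6* differed by −3.33 (SE 0.37). Of 42 tested cell cycle genes 36 were lower and 0 higher, with a list median of −1.29 that was −1.26 with the deposited scaling and −0.48 with median centring, where 16 were called lower and 1 higher (*CDC25B*, +0.82). *TFRC*, the transferrin receptor, was lower too (−2.02, SE 0.14).

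Several genes of amino acid synthesis and transport, picked after their values were seen, were higher on the same arrays. *ASNS*, asparagine synthetase, averaged 325 against 4105 on the arrays numbered 3 (log2 +3.62, SE 0.28, adjusted p = 0.00028). The pseudokinase *TRIB3* differed by +3.01 (SE 0.21), the serine synthesis enzyme *PSAT1* by +2.84 (SE 0.23), the glutathione-degrading enzyme *CHAC1* by +4.31 (SE 0.40) and the amino acid transporters *SLC7A11* and *SLC7A5* by +2.50 (SE 0.48) and +3.12 (SE 0.63). *ATF4*, their shared transcription factor, differed by +0.87 (SE 0.15). Of 23 tested genes of the unfolded protein and amino acid stress list, 11 were higher and 1, the endoplasmic reticulum chaperone *HSP90B1*, was lower; it was 11 and 3 with the deposited scaling and 15 and 0 with median centring, where *HSP90B1* was at −0.02. With an estimated correlation the adjusted p = 0.26 for this list. In the interferon list 5 of 27 genes were higher and 0 lower, and 11 higher with median centring, among them the antigen presentation genes *PSMB8* (+2.01, SE 0.27), *HLA-B* (+1.08, SE 0.16) and *TAP1* (+1.28, SE 0.25). The cytokines *IL24* and *IL1A* were higher by 2.51 (SE 0.27) and 2.95 (SE 0.46), in an inflammatory list with 5 of 21 genes higher and 0 lower. It was 5 and 2 with the deposited scaling, where *PTGS2* was at −2.05 and *TNF* at −1.88, and 11 and 1 with median centring. The genes named in this paragraph, *HSP90B1* included, kept their direction with the deposited scaling and with median centring, which moved the median of all tested probe sets to −0.33 and +0.45. With a preset correlation 7 lists were called, and 0 with an estimated correlation (lowest adjusted p = 0.26).

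The tables argue against 3 technical origins of the difference at number 3, of which scaling was weighed for the cell cycle genes alone. An error of single probe sets would leave a gene's second probe set free to go either way, but 93.9% of the 294 called genes with a second tested probe set had it going the same way, against 71.4% of all 2525 genes with 2 tested probe sets. A scaling of whole arrays moves probe sets of one brightness alike, but with the deposited scaling the cell cycle list lay at −1.29 from probe sets of its brightness (−1.15 with mock vector, −1.53 with siRNA). The unfolded protein and amino acid stress list lay at only +0.36 (+0.57 with mock vector, +0.30 with siRNA), with 16 of 23 members above. Scaling thus stays open for probe sets outside the cell cycle list. RNA degradation would move the 3′ to 5′ ratios, and 0 of 4 ratios on these arrays lay outside the range of the other arrays. Slower growth of the cells behind the arrays numbered 3 is a hypothesis that arose from these values and was not tested on others. The labels do not say whether these arrays came from separate cultures. A shared day of culture or labelling stays open, and no biological explanation from the design was tested.

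The lower heat shock list may rest on a single array, and whether it rests on correlated members could not be decided. Without seprase siRNA array 3 its adjusted p was 0.516 and 6 of its 12 members lay below 0, and with an estimated correlation the adjusted p was 0.881. The estimated correlation called 0 lists in every split of the 6 arrays, and 0 on the arrays numbered 3. Its outcome therefore cannot tell correlated members from a change of the list. Over all 22 alternatives the adjusted p ran from 4.2e-07 to 0.915. An effect of the siRNA stays open as well. The 2 array control probe sets for Cre that had passed were also lower with siRNA (log2 −0.29 and −0.33), by more than the list's median of −0.12. They are named because they passed, and other controls are not shown. Deposited signals of the first overlapped between the groups, with siRNA array 2 at 20443 and mock vector array 1 at 17544.

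Metallothioneins, metal-binding proteins induced by zinc and stress, read higher with seprase siRNA on all 12 tested probe sets with the main and the deposited scaling, and on 6 of 12 with median centring. *MT1X* read 2079 ± 294 with mock vector and 3031 ± 753 with siRNA (SD, n = 3; log2 +0.61, SE 0.22), a brighter *MT1X* probe set gave +0.30 (SE 0.09), and *MT2A* differed by +0.09 (SE 0.08); none passed the threshold (adjusted p = 0.9997). Their excess over probe sets of the same brightness was 0.42 with the deposited scaling. Median centring shifts each array by a constant, so it gives the same excess and adds no second result. In the 3 pairs the excess was 0.23, 0.23 and 0.76, with 11 of 12 probe sets above 0 in each. The rule set before, a bound of 0.22, was met on the side against scaling. Comparing probe sets of one brightness already takes out most of a whole-array scaling, so the bound was likely to be passed and decides little. A requirement on the spread between pairs was added after the excess was seen, and it was not met (mean 0.41, SE 0.18, t = 2.32, 4.30 needed). Scaling was therefore not excluded by more than that spread. Hybridisation shared by the gene family cannot be told apart from a rise of these genes. Of the 12 probe sets, 10 can bind related transcripts, and the remaining ones, for *MT3* (+0.37, SE 0.49) and *MT1G* (+0.48, SE 0.61), were too imprecise. A response to the siRNA is a hypothesis that these arrays leave open.

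The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 probe sets and the highest of the others 0, so all 10 gave as many. It called 1 gene list and the highest of the others 7, and all 10 splits called at least 1. At an unadjusted p under 0.05, the 4 splits that kept the arrays numbered 3 together gave 915 to 2037 probe sets. The 6 that parted them gave 160 to 342, with 276 for the real split, which points to the arrays numbered 3 standing apart. Among the 4 splits that part all pairs, with the replicate number as a block, the real split called 3 lists and the others 2 to 3.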
